A study of Danio rerio with 3 samples.

How the data were processed

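Single-cell RNA of adult zebrafish pituitaries was measured in 3 libraries made with the 10x Genomics 3' version 2 chemistry. The pool held pituitaries of 6 males and the single-male library 1 pituitary; both were Sox17:CreERT2 fish with a floxed EGFP-to-mCherry cassette, given 5 uM 4-hydroxytamoxifen from 4 hours post fertilization for 2 h and taken at 6 months. The transplant library came from 3-month-old mosaic fish, with donor cells carrying the same cassette without Cre and hosts carrying a TagBFP-to-dsRed cassette; the number of these fish and their sex are not given in the sources used here. Per the submitters' processing notes, Cell Ranger 3.0.0, Seurat 2.4.0 and the GRCz11 assembly were used. The deposited values are UMI counts per gene and barcode, as whole numbers without normalization, for barcodes called as cells. The role of Seurat and the sequencing depth in reads are not given in the sources used here.

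The pool held 7987 barcodes and 24731718 UMIs (median 2687 UMIs and 967 genes), the single male 5587 barcodes and 14426387 UMIs (2348 and 916), and the transplant 8882 barcodes and 48744705 UMIs (4504.5 and 1175). EGFP and mCherry were features of all 3 libraries; TagBFP and DsRedExpress were features of the transplant alone. The transplant had the greatest depth, so a share of cells with a UMI is easier to reach there. Of the 32524 features, 29201 (89.8%) matched the gene names used, and 598 symbols stood on several identifiers. Of 369 listed genes 363 were matched, 356 by symbol, 5 by gene identifier and 2 by a RefSeq synonym; cpeb, gnrhr3, juna, scg2a, trac and tshbb were not matched.

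Barcodes with at least 200 genes and at most 20.0% mitochondrial UMIs were kept, which removed 17, 10 and 31 barcodes in pool, single male and transplant. Doublets were called within each library by Scrublet in scanpy with an expected rate of 0.06. Its automatic threshold marked under 0.5% of barcodes in both Sox17 libraries, where a score of 0.25 was used, as fixed beforehand. The calls removed 229 (2.87%), 125 (2.24%) and 257 (2.90%) barcodes. All libraries were clustered together without the reporters: 10000 counts per cell, logarithm, 2000 highly variable genes with library as batch, 30 principal components, 15 neighbours and Leiden resolution 1.0, with no integration and seed 1. This gave 22 clusters. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.

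Clusters were named from 23 marker lists by the genes above other cells of the same library, with a pseudocount of 10 CPM. Hormone classes were named by the hormone gene with the highest ratio, and for pomca by oacyl or pax7a (melanotroph-like) or gad2. Other names needed 3 markers of their list, with at least 1 list member among the 10 leading genes. The marker lists were fixed before the data were examined, but the scoring and its thresholds (log2 ratios of 3 for hormones, 2 for other markers and 1 for pomca) were set after the clusters had been seen. A second rule, against the median cluster of the library, put 96.7% of cells in the same class. Clusters 3, 6 and 11 met no rule and stayed unnamed; cluster 6 had a low UMI count.

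A cell was called mCherry-only, EGFP-only, donor (EGFP without TagBFP or DsRedExpress) or host (the reverse) from at least 1 UMI of the one and 0 of the other. Shares carry exact binomial (Clopper-Pearson) 95% intervals. Shares of mCherry-only cells were given for classes with at least 30 cells with 1 mark. Shares of donor cells were given for transplant classes with at least 30 cells. A limit given beside 0 cells is 3 over the number of cells, which in the cases below is lower than the exact upper bound. The shares of mCherry-only and donor cells were repeated on cells thinned to 1500 UMIs. Expected shares of double-marked cells were taken from cells of the same class and depth. Expression was compared as ratios of UMI sums per total UMIs with exact conditional Poisson 95% intervals; a count of 0 was set at 3 counts over the group to give a bound. mCherry-only and EGFP-only cells were compared in classes with at least 50 of each, on genes with at least 20 UMIs; libraries were compared on genes with at least 50 UMIs in the higher library. No pool or transplant class had 50 cells of each kind, so donor and host cells were not compared in expression. Cells are not replicates and each group had 1 library, so no p-values and no counts of changed genes were computed.

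Gene lists fixed before the data were examined covered pituitary hormones, secretory granule and prohormone processing, pituitary transcription factors, endoderm and foregut genes, placode and oral ectoderm genes, pituitary hormone receptors, immediate early genes, heat shock and proteostasis, ER stress and unfolded protein response, mitochondrial transcripts, interferon and antigen presentation, the core circadian clock, glycolysis and the cell cycle. A list with at least 5 measured members has its median log2 ratio and the percentile of that median among 10000 random lists matched on mean expression in 20 bins. The random lists treat genes as independent. An extreme percentile can thus come from few cells in which list members move together. Ratios of hormone genes were computed in every compared class, and only some of them are given below. Between libraries, in the largest class compared (somatolactotroph-like), the 10 higher and 10 lower genes by the bound of the interval nearest 1 were named, and 2 to 4 members of each list. 1 of these higher genes, and 1 marker of the stem-like cluster on which its name rests, are not reported here. For mCherry-only against EGFP-only cells the rule fixed beforehand needed both Sox17 libraries and could not be met; instead the 5 higher and 5 lower genes of the single male were named, with the pool ratio beside them, a choice made after seeing the data.

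The ratio method was tested on simulated data made from these libraries. Counts were drawn as Poisson around class means, without variation between cells. The values below thus do not show how the intervals hold where a few cells make most of a count. Intervals of unchanged genes held the true value in 95.7%, 95.9% and 95.3% of cases for transplant against pool, transplant against single male and single male against pool, and in 95.8% for mCherry-only against EGFP-only cells. A planted 2-fold change was found in 98.8%, 96.2%, 96.6% and 70.2% of genes, and a 4-fold change in 96.5% in the last and 100.0% in the others. Of 40 unshifted lists, 1, 1, 5 and 3 lay outside the central 95%.

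Alternatives chosen before the data were examined were no filter, a filter at 500 genes and 10.0% mitochondrial UMIs, doublets kept, 2 UMIs per reporter call, the majority or share of reporter UMIs, thinning to 1000 or 3000 UMIs, Leiden resolutions 0.5 and 2.0, each library clustered alone, hormone genes left out of the clustering, totals without hormone or mitochondrial genes, median-ratio scaling, no count minimum and a minimum of 100 UMIs. Alternatives added after seeing the data were the second naming rule, names given afresh to each clustering, leaving out the highest cell of each group, and leaving out cells with 3 or more UMIs of the second scg5. Elsewhere the names of an alternative clustering were carried over by majority. Sequence reads were not used here.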

Results

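Cells of adult zebrafish pituitaries were profiled in 3 libraries that trace endoderm-derived cells by different marks. In the pool of 6 males and in the single male, Cre under the sox17 promoter switched a ubiquitous cassette from EGFP to mCherry in the embryo. In the transplant, EGFP donor cells steered towards endoderm by taram-a mRNA were placed in TagBFP host embryos. After filtering, 7741 cells of the pool, 5452 of the single male and 8594 of the transplant were kept, with median depths of 2663, 2333 and 4437 UMIs per cell. Each design group was 1 library, so there were no replicates, and intervals below cover counting error only. Strategy, transgenic lines, age, number of fish and depth were not separated. Nor was sex, which is not given for the transplant.

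The main hormone-producing cells of the pituitary were found in each library. Clusters led by tshba (thyroid-stimulating hormone beta) and dio2 were called thyrotroph-like, and those led by oacyl and pax7a with pomca (proopiomelanocortin) melanotroph-like. Clusters led by lhb or fshb (gonadotropin beta subunits) were called gonadotroph-like, and those led by smtla and smtlb (somatolactins) somatolactotroph-like. A cluster led by genes that include her4.1, with her6, sox3 and cldnb, was called stem-like. The 3 remaining endocrine groups are named by their genes: prl (prolactin), gh1 (growth hormone), and pomca with gad2. Of these, gad2 but not pomca was among the leading genes of the pomca-gad2 clusters. Most endocrine classes lay in separate clusters in the Sox17 libraries and in the transplant. Thyrotroph-like and stem-like cells of all 3 libraries shared 1 cluster each.

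Gonadotroph-like cells were 12.8% (95% interval 12.1 to 13.6) of the pool, 4.95% (4.39 to 5.56) of the single male and 23.7% (22.8 to 24.6) of the transplant. With libraries clustered alone and named afresh, a setting added after seeing the data, they were 5.41% of the transplant, where 35.2% of cells were then unnamed. In the transplant, 1436 of these cells formed an lhb-led cluster and 480 a cluster with fshb and mdka (the fshb-led cluster below). The other 118 lay in cluster 0, also led by fshb, which held nearly all gonadotroph-like cells of the Sox17 libraries. The gh1-high cells were 9.93% of the pool and 9.79% of the single male, mostly in cluster 10. Fresh names at Leiden 2.0, also added, gave 5.74% and 5.45%, and 10.3% of the transplant. In the transplant 19.98% were gh1-high by the main setting, mostly in cluster 17, which had the globin genes hbba1 and hbaa1 among its 10 leading genes; its share is not compared with those of cluster 10. The pomca-gad2 cells were 18.5% of both Sox17 libraries and 6.45% of the transplant, and prl-high cells were 16.5%, 15.6% and 8.56% of pool, single male and transplant. Somatolactotroph-like cells were 17.6% of the pool and of the transplant and 22.7% (21.6 to 23.9) of the single male. Melanotroph-like cells were 7.52%, 9.74% and 7.69% of pool, single male and transplant, thyrotroph-like cells 4.66%, 3.34% and 5.53%, and stem-like cells 4.17%, 6.77% and 4.12%. Pituicyte-like cells stayed under 1% of each library (0.801%, 0.734% and 0.849%), and endothelial-like cells were 0.245%, 0.312% and 0.593%. Mural-like cells were 0.0517%, 0.0550% and 0.326%, and macrophage-like cells 0.103%, 0.0734% and 0.175%. Cells of unnamed clusters were 7.07%, 7.48% and 4.42%. Hormone genes help to define these classes and also differed in level between libraries; with hormone genes left out of the clustering, 33 of 39 class shares stayed within their interval.

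mCherry-marked cells were present in both Sox17 libraries and were far more frequent in the single male. In the pool, 150 cells (1.94%; 1.64 to 2.27) held mCherry without EGFP and 2035 (26.3%) held EGFP without mCherry. The single male had 440 mCherry-only cells (8.07%; 7.36 to 8.83) and 643 EGFP-only cells (11.8%). Among cells with 1 reporter, the mCherry share (the conversion share) was therefore 6.86% in the pool and 40.6% in the single male, in the order of the submitters' moderate and high conversion. Both reporters were seen in 33 pool cells and 25 single-male cells. mCherry was found in 1.60% of pool cells with EGFP, against 3.43% expected from class and depth, and in 3.74% against 10.7% in the single male. No mCherry UMI was found in the 8594 transplant cells, of which only the rare donor cells (67 called) carry the cassette. Reporter transcripts were sparse: 71.3% of pool cells and 79.7% of single-male cells held neither, so the shares describe cells with a detected reporter.

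Cells called mCherry-only were found in every endocrine class with enough cells in both Sox17 libraries, and in stem-like cells. No background was taken off: in the pool, mCherry was found in 1.203% of melanotroph-like, 1.47% of somatolactotroph-like and 1.56% of gh1-high cells, no more often than in pool cells with EGFP (1.60%). The calls in these 3 pool classes are thus not told apart from background. This background was not matched on depth. Pool EGFP-only cells had a median of 3288 UMIs, against 2209 in gh1-high, 2569 in somatolactotroph-like and 4918 in melanotroph-like cells. Pool stem-like (2.17%; 0.876 to 4.41) and gonadotroph-like cells (2.42%; 1.56 to 3.58) had intervals that also held 1.60%. In the single male, mCherry was found in 3.74% of cells with EGFP (2.44 to 5.48). The gh1-high calls there (mCherry in 4.49% of cells; 2.901 to 6.61) are not told apart from this background either. It was not matched on depth: single-male EGFP-only cells had a median of 2854 UMIs and gh1-high cells 1969. Intervals of single-male gonadotroph-like (6.67%; 3.999 to 10.3) and melanotroph-like cells (7.34%; 5.27 to 9.90) lay above 3.74% but reached below 5.48%. In the single male the conversion share was highest in stem-like cells, at 66.7% (62 of 93; 56.1 to 76.1; no cluster was called stem-like with fresh names at Leiden 2.0), and in melanotroph-like cells, at 60.9% (39 of 64; 47.9 to 72.9). Somatolactotroph-like cells followed with 55.0% (126 of 229; 48.3 to 61.6), then prl-high cells with 48.2% (66 of 137; 39.6 to 56.9) and thyrotroph-like cells with 37.8% (17 of 45; 23.8 to 53.5). The melanotroph-like share goes with few EGFP cells: of all cells of that class 7.34% (5.27 to 9.90) held mCherry and 4.71% EGFP, against 7.35% and 19.6% of pomca-gad2 cells and 17.3% and 8.94% of stem-like cells. Per total UMIs, mCherry in melanotroph-like cells was 0.528 times that of the rest (0.386 to 0.708), and in stem-like cells 2.22 times (1.77 to 2.75). The conversion share was lowest in gh1-high cells (22 of 112, 19.6%; 12.7 to 28.2), gonadotroph-like cells (12 of 54, 22.2%; 12.04 to 35.6) and pomca-gad2 cells (68 of 259, 26.3%; 21.0 to 32.1). In the pool, prl-high cells had the highest share, 14.9% (38 of 255; 10.8 to 19.9), and gonadotroph-like cells the lowest, 3.23% (15 of 464; 1.82 to 5.28). The other pool classes were thyrotroph-like at 11.6% (6.33 to 19.0), pomca-gad2 at 8.64% (6.18 to 11.7) and stem-like at 7.32% (2.73 to 15.2). Pool melanotroph-like, gh1-high and somatolactotroph-like cells lay at 4.70%, 4.66% and 4.50%, with overlapping intervals.

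The order of the classes was shared by both Sox17 libraries only in part. Against all other cells of the same library, prl-high cells had a conversion share higher by 9.10 percentage points in the pool and 8.64 in the single male. This was 2.57 times the share of the rest in the pool (5.80%) but 1.22 times in the single male (39.5%). In the single male the intervals of class and rest overlapped. The differences for gh1-high cells were -2.42 and -23.4 points, and those for gonadotroph-like cells -4.61 and -19.4 points. Stem-like cells were above the rest by 0.470 points in the pool and 28.5 points in the single male. In cells thinned to 1500 UMIs, which left out 1429 pool cells and 1139 single-male cells, the prl-high share was 16.1% in the pool and 51.7% in the single male. Thinned gh1-high cells gave 4.92% and 17.1%, pomca-gad2 cells 8.16% and 24.4%, and somatolactotroph-like cells 3.48% and 61.8%. The thinned stem-like share was 79.1% (34 of 43) in the single male. Non-endocrine cells with a reporter were too few for a share: 0 of 8 endothelial-like, 0 of 11 pituicyte-like and 1 of 4 macrophage-like pool cells with 1 reporter held mCherry.

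**Figure D1:**
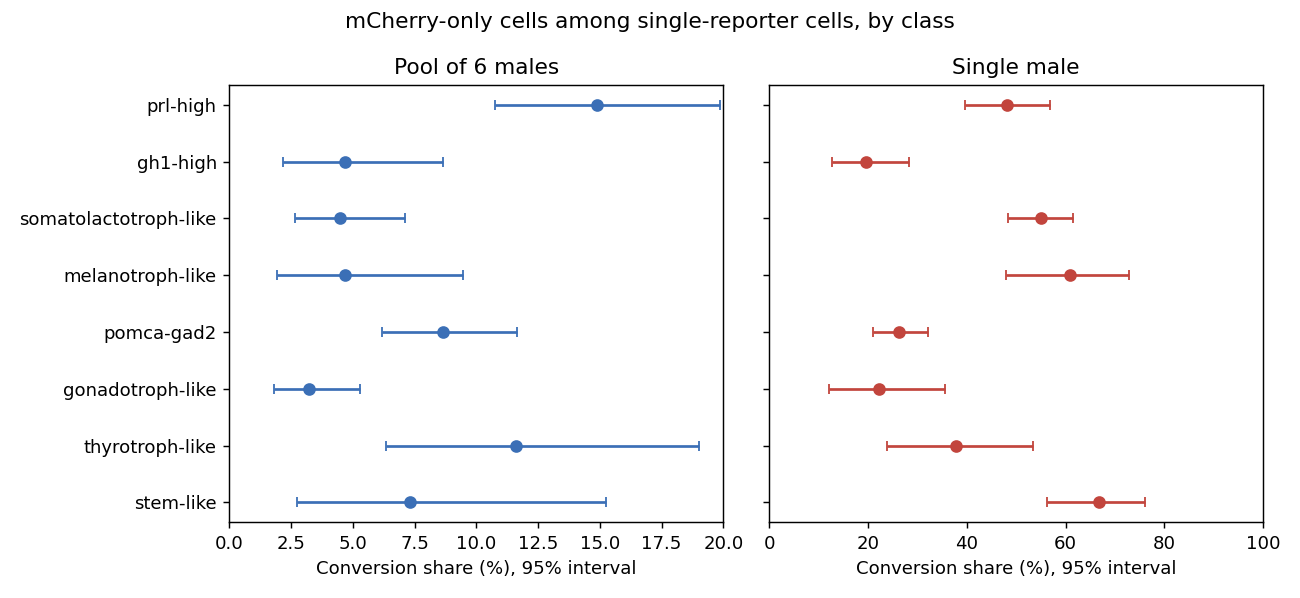
Share of mCherry-only cells among cells with 1 detected reporter, in percent with 95% binomial intervals, by cell class, for the pool of 6 males (left, axis to 20%) and the single male (right, axis to 100%). In the pool the prl-high class is highest at 14.9%, and in the single male the stem-like class is highest at 66.7%.

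Cells called donor by EGFP were rare in the transplant pituitaries and lay in several endocrine classes. Of 8594 cells, 67 (0.780%; 0.605 to 0.989) held EGFP without a host reporter, 2798 (32.6%) held a host reporter only, and 9 held both. The donor share among cells with 1 mark was 2.34%. It was 5.21% in prl-high cells (10 of 192; 2.53 to 9.37), 4.89% in pomca-gad2 cells (9 of 184; 2.26 to 9.08) and 3.81% in somatolactotroph-like cells (25 of 657; 2.48 to 5.57). Stem-like cells had 2 donor cells of 52 (3.85%) and thyrotroph-like cells 3 of 168 (1.79%). In gh1-high cells, nearly all of cluster 17, the share was 0.564% (4 of 709; 0.154 to 1.44) and in melanotroph-like cells 0.567% (2 of 353; 0.0687 to 2.03), with intervals below those of prl-high and somatolactotroph-like cells. Gonadotroph-like cells had 3.54% (11 of 311; 1.78 to 6.24). All 11 of these donor cells lay in the fshb-led cluster (11 of 171, 6.43%; 3.25 to 11.2), while the lhb-led cluster had 0 of 134, a limit of 2.24%, and cluster 0 had 0 of 6. No donor cell was seen among 43 endothelial-like and 24 pituicyte-like cells, which leaves limits of 6.98% and 12.5% (exact upper bounds 8.22% and 14.2%).

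The donor call rests mostly on single UMIs, since 97 EGFP UMIs were found in 76 cells. EGFP was found in 0.324% of cells with TagBFP (0.148 to 0.615), against 1.15% of cells without it and 1.23% expected from class and depth. No background was taken off, and with EGFP in 0.349% of gh1-high and 0.303% of melanotroph-like cells the donor calls of these classes are not told apart from it. The 2 donor calls among 354 stem-like cells and the 3 among 475 thyrotroph-like cells are also too few to be told apart from background. In cells thinned to 1500 UMIs, which left out 856 cells, the donor share fell to 1.73% overall. The thinned share was 4.29% in prl-high, 2.75% in somatolactotroph-like, 5.13% in pomca-gad2 and 0.487% in gh1-high cells, and no thinned melanotroph-like donor cell remained. In gonadotroph-like cells it was 0.952% (2 of 210), against 3.54% before thinning. The thinned gh1-high interval (0.0590 to 1.75) overlapped those of prl-high (1.59 to 9.09) and somatolactotroph-like cells (1.51 to 4.56). With at least 2 UMIs asked of a reporter, the donor share was 0.750%.

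TagBFP was detected unevenly across host classes, in 84.3% of endothelial-like cells but 14.1% of stem-like and 14.5% of gonadotroph-like cells. A class with little TagBFP contributes few host cells to the donor share, so the shares of stem-like and gonadotroph-like cells rest on a small part of each class. Of all cells of a class, EGFP was found in 1.78% of somatolactotroph-like (1.18 to 2.58), 1.81% of pomca-gad2 (0.869 to 3.29) and 1.36% of prl-high cells (0.653 to 2.48). It was found in 0.349% of gh1-high (0.128 to 0.759), 0.303% of melanotroph-like (0.0367 to 1.09) and 0.541% of gonadotroph-like cells (0.270 to 0.966), whose median depths were greater. Among all gonadotroph-like cells, EGFP was found in 11 of 480 cells of the fshb-led cluster (2.29%; 1.15 to 4.06), in 0 of 1436 of the lhb-led cluster, a limit of 0.209%, and in 0 of 118 of cluster 0. The transplant cells of cluster 0 had a median of 1114.5 UMIs, against 5672 in the fshb-led cluster, so EGFP was harder to detect in them.

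**Figure D2:**
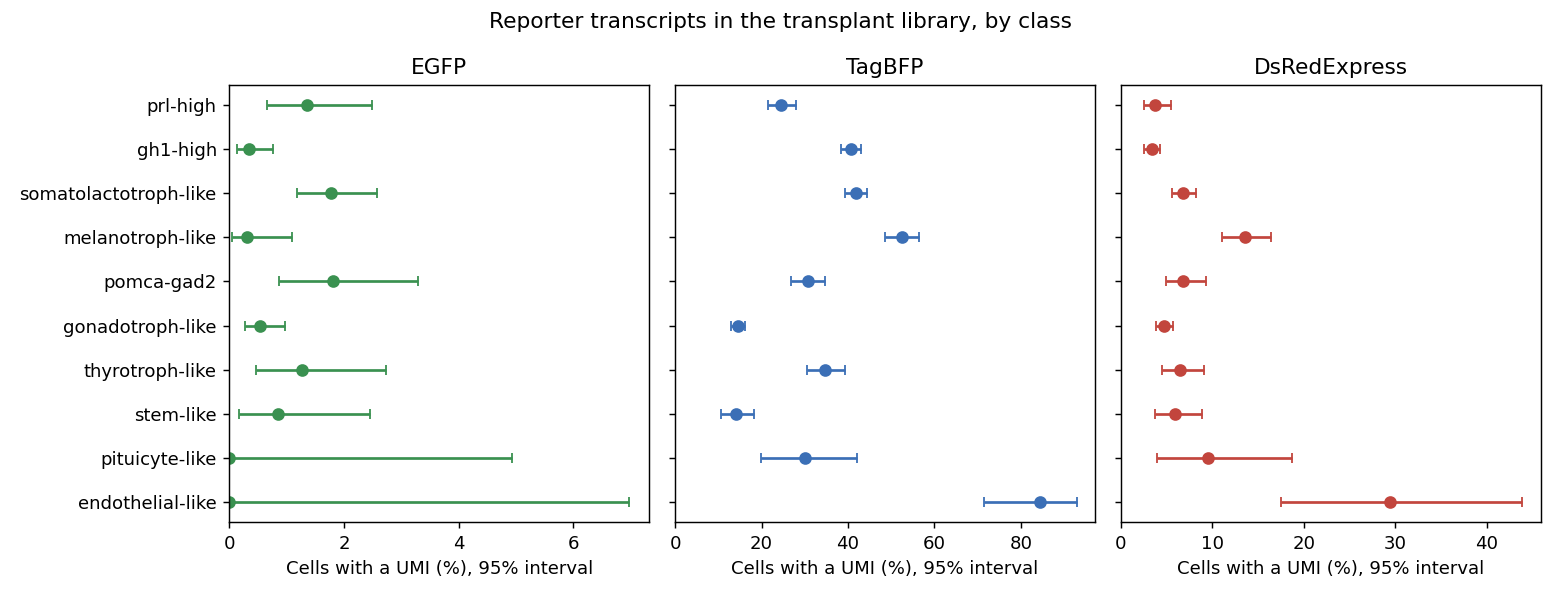
Share of transplant cells with at least 1 UMI of EGFP, TagBFP or DsRedExpress (panels, in percent with 95% binomial intervals, each with its own axis), by cell class. TagBFP was detected in 84.3% of endothelial-like cells and in 14.1% of stem-like cells.

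Within a class of the single male, mCherry-only and EGFP-only cells had similar levels of the leading hormone in prl-high and pomca-gad2 cells, while somatolactotroph-like cells differed in both somatolactins. Only the single male had 50 cells of each kind in a class, in 3 classes: somatolactotroph-like (126 against 103 cells), prl-high (66 against 71) and pomca-gad2 (68 against 191). The log2 ratio of mCherry-only over EGFP-only cells for prl in prl-high cells was -0.19 (-0.22 to -0.16), and for pomca in pomca-gad2 cells -0.09 (-0.11 to -0.08). The pool gave 0.18 (0.17 to 0.20) for prl and -0.016 (-0.031 to -0.0023) for pomca, so the prl direction was not shared. In somatolactotroph-like cells, smtla was higher in mCherry-only cells (0.67; 0.60 to 0.74) and smtlb lower (-1.25; -1.28 to -1.22). Without cells of 3 or more UMIs of the second of 2 genes named scg5, a setting added after seeing the data, these came to 1.27 and -1.39. The pool gave 0.09 for smtla and 0.72 for smtlb, so the smtlb direction was not shared. In these cells prl had a ratio of 0.37, which came to -0.27 with doublets kept, and pomca of 0.06. The pool, with 17 mCherry-only cells in this class, gave 2.65 for prl and -0.13 for pomca.

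The lists of immediate early and clock genes had medians below 0 in mCherry-only somatolactotroph-like cells, though the intervals of most members held 0. Of 17 measured immediate early genes, which respond within minutes to stimulation, 12 had a ratio below 0; 6 had an interval below 0 and 1 an interval above it. The list median was -0.44, below all 10000 matched random lists (percentile 0.00), and the members' interval bounds had medians of -1.01 and 0.18. The random lists do not account for members that vary together between cells. For mCherry-only over EGFP-only cells, list medians were computed in the single male alone. They were not repeated without the highest cell of each group. Of 10 measured clock genes 8 had a ratio below 0, 2 of them with an interval below 0; the median was -0.54 (percentile 0.33) and the bounds -1.65 and 0.53. fkbp5, a glucocorticoid-induced co-chaperone, had a log2 ratio of -1.62 (-2.10 to -1.15; 53 against 138 UMIs), and the pool gave -0.24. cfp, which encodes the complement factor properdin, was lower at -1.56, but higher in the pool at 1.03. stmn4, a stathmin that binds tubulin, was lower at -1.58 (pool -0.027), and wu:fj16a03 at -1.20, with a pool value of -1.72 (-2.43 to -1.08). Higher genes were crtac1a, a cartilage acidic protein gene (0.97; 0.66 to 1.28), tusc3, an oligosaccharyltransferase subunit gene (1.47), AL954359.2 (1.51) and si:ch211-161h7.5 (2.25); the pool gave -0.17, -0.11, 0.72 and -0.26 in this order. Of 2 genes named scg5 (secretogranin V, a chaperone of prohormone convertase), the first was higher at 0.73 (0.66 to 0.80; pool 0.18) and the second lower at -6.40 (pool -1.72), with 429 UMIs in 9 EGFP-only cells.

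The medians of other lists in somatolactotroph-like cells lay nearer to 0. They were 0.06 for hormones (percentile 62.7), -0.14 for secretory granule genes (4.00), 0.07 for pituitary transcription factors (58.5) and 0.11 for heat shock genes (93.7), of which 5 of 13 had an interval above 0 and 0 below. ER stress genes had a median of -0.06 (20.7), mitochondrial transcripts 0.12 (91.8), interferon genes 0.01 (29.9) and glycolysis genes 0.02 (37.0).

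In prl-high cells, the genes higher in mCherry-only cells included zbtb16a, a zinc finger repressor (1.96; 0.71 to 3.41), adm2a, an adrenomedullin peptide gene (1.22), adh5 (1.22), the linker histone gene h1f0 (1.37) and zgc:158463 (1.34). The pool gave 0.61, -0.45, 0.079, -0.79 and -0.51 in this order. The tight junction gene cldnb had 0 UMIs against 23, at least 7.06-fold lower. prss1, a trypsin gene, was lower at -1.80, cdk2ap2 at -3.13, CR936442.1 at -3.66 and the second scg5 at -4.40. The pool gave -0.27 for cldnb, 0.34 for prss1, 0.25 for cdk2ap2, -1.34 for CR936442.1 and -1.85 for the second scg5. Of these low values, 3 rest on few EGFP-only cells: 1 cell held 17 of the 23 UMIs of the second scg5 and 1 held 11 of the 19 of cdk2ap2, and 5 cells held the 55 of CR936442.1. Of 15 immediate early genes 12 had a ratio below 0, 3 of them with an interval below 0; the median was -0.29 (percentile 0.45) and the bounds -0.82 and 0.24. The other medians were -0.19 for hormones (1.09), -0.08 for secretory granule genes (27.2), -0.14 for heat shock genes (1.73), 0.12 for ER stress genes (79.0), -0.14 for mitochondrial transcripts (3.87) and 0.12 for glycolysis genes (74.4). The gh1 ratio of 5.03 came from 1 cell with 2495 of 2588 UMIs and was 0.32 without the highest cell of each group.

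In pomca-gad2 cells, immediate early genes (-0.09; percentile 1.92) and clock genes (-0.02; 29.3) lay near 0. Hormones had a median of -0.44 (0.00), made by genes foreign to the class such as lhb (-2.51), cga and tshba (-1.40); lhb came to -0.21 and tshba to 0.25 without the highest cell of each group, and the hormone median turned to 0.30 with doublets kept. Higher in mCherry-only cells were clk2a, a kinase of splicing factors (1.97), hpf1 (2.00), the calcium-binding protein gene cabp5a (1.09), the transketolase gene tktb (1.85) and actl6a (1.70). The pool gave -1.24, -1.29, -0.54, 0.31 and -0.84 in this order. rgs16, a regulator of G protein signalling, was lower at -2.37 but higher in the pool at 0.94. srsf9 (-3.41), copz2 (-2.24) and zgc:158343 (-2.04) were lower, and trappc6b had 0 UMIs against 20 (at least 2.21-fold lower); the pool gave -0.46, 0.26, 0.046 and -0.21. In EGFP-only cells 1 cell held 36 of the 78 UMIs of rgs16, and 1 cell 28 of the 62 of zgc:158343. List medians were -0.21 for secretory granule genes (0.46), 0.10 for heat shock genes (97.0), 0.14 for mitochondrial transcripts (99.1) and -0.24 for hormone receptors (15.5). Transcription factors had -0.04 (27.5), ER stress genes 0.00 (36.3), interferon genes 0.00 (41.2) and glycolysis genes -0.06 (11.2). Of the 30 genes named in the 3 classes by the interval bound nearest 0, 14 had the same direction in the pool. Unrelated directions would give about as many. In 4 the pool interval lay on that side: the second scg5 in prl-high and somatolactotroph-like cells, the first scg5 in the latter, and wu:fj16a03. In 2 genes the pool interval lay on the opposite side. The pool mixed 6 fish and its cells were not assigned to fish. The 4 on the same side are thus not told apart from differences between fish. In somatolactotroph-like cells the second scg5 and wu:fj16a03 also differed between single male and pool (-3.85 and -2.95).

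Somatolactotroph-like cells of the transplant had lower levels of clock genes than those of both Sox17 libraries, and of heat shock genes than those of the pool. Hormone receptor and secretory granule genes were lower too at the main count minimum. These cells were cluster 4 in the transplant and cluster 2 in the Sox17 libraries. The median log2 ratio of all genes was shifted, by -0.37 against the pool and -0.32 against the single male, and list medians and counts of list members below are given relative to it. Of 15 measured clock genes 14 were lower against the pool, 11 with their interval, at a relative median of -1.08 (percentile 0.00). Against the single male 11 of 13 were lower, all with their interval (-0.81; 0.18). The nuclear receptor gene nr1d1 had a log2 ratio of -2.54 against the pool, and the period gene per3 -2.33 against the pool and -2.04 against the single male. Clock genes were also lower in transplant melanotroph-like (-1.39), gonadotroph-like (-1.22) and thyrotroph-like cells (-1.03) against the pool. Hormone receptor genes were lower in 4 of 5 cases against the pool (3 with their interval) and 5 of 5 against the single male (4), with relative medians of -1.13 (0.33) and -1.14 (0.34); they included the oestrogen receptor genes esr1 (-2.64 against the pool, -3.13 against the single male) and esr2b (-2.46 and -2.40). This median was -0.10 against the pool and -0.23 against the single male with no count minimum.

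Of 13 heat shock genes 9 were lower in the transplant than in the pool, all 9 with their interval (relative median -0.47; 0.09), among them hsp90aa1.2 (-2.69) and dnajb1b (-2.57). Against the single male 8 of 13 were lower, but the relative median was -0.06 (2.02), and 0.26 with no count minimum. Secretory granule genes were lower in 9 of 12 cases against the pool, 8 with their interval (-0.40; 0.37), and in 7 of 11 against the single male, all 7 with it (-0.35; 1.01), scg3 among them at -0.75 and -0.69; with no count minimum the median against the single male was -0.043. Immediate early genes did not move together: 12 were higher and 8 lower than in the pool (0.30; 87.1), with atf3 higher at 1.57 and dusp1 lower at -1.97. Against the single male their relative median was 0.47 (99.02), with the cytokine signal suppressor gene socs3a at 1.89. ER stress genes had relative medians of -0.36 (0.62) and 0.08 (29.9), mitochondrial transcripts 0.04 (17.6) and 0.04 (4.47), and interferon genes 0.43 (87.6) and 0.26 (39.3). The interferon median against the pool turned to -0.18 at 100 UMIs and -0.011 after thinning to 1500 UMIs, and the mitochondrial one against the single male to -0.078 and -0.035. Transcription factors had -0.38 (7.67) and -0.07 (13.5), placode genes -0.01 (30.1) and 0.47 (85.8), and glycolysis genes -0.10 (5.07) and 0.29 (71.8), with gapdh at -2.20 and -1.69.

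In transplant somatolactotroph-like cells the somatolactin gene smtlb had a higher level and smtla a lower one. smtlb had a log2 ratio of 2.03 against the pool and 1.84 against the single male, and smtla of -1.62 and -1.31. The hormone list had relative medians of 0.33 (58.2) and 1.80 (100), but most of its members are made by other classes, and the share of free RNA in their UMIs was not estimated. This holds also for gh1 in classes that are not led by it, with ratios against the pool of 5.03 in thyrotroph-like, 2.11 in gonadotroph-like and 2.92 in stem-like cells. In their own classes, lhb was higher by 0.72 against the pool, fshb was -0.30, tshba 0.68 and melanotroph-like pomca 0.20.

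The single genes that set transplant somatolactotroph-like cells apart went the same way in all other cells combined. The class I histocompatibility gene mhc1uba had log2 ratios of 5.89 against the pool and 8.31 against the single male, and 6.02 and 7.67 in all other cells. FP236812.2 (6.24 and 7.38), the potassium channel subunit gene kcne4 (6.68 and 4.99) and fastkd2 (4.54 and 4.27) were higher, as was a histone gene named hist1h4l under 2 identifiers (3.82 and 6.31 for 1 of them). The other hist1h4l identifier had no UMI in the Sox17 libraries, at least 28.1-fold and 23.2-fold higher. CU929451.1 was at least 48.9-fold and 40.4-fold higher. si:busm1-266f07.2 had 6.93 against the pool and was at least 67.1-fold higher than in the single male. si:dkey-19a16.7 had 6.21 and was at least 20.4-fold higher.

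Lower in the transplant were apodb, an apolipoprotein D gene (-9.37 and -8.80) that also leads the Sox17 cluster, and the second scg5 (-10.01 and -6.17). The lactate carrier gene slc16a1a (-5.64 and -5.98) and the collagen gene col12a1b (-5.81 and -5.20) were also lower. Lower too were si:dkey-264f17.4 (-6.71 and -8.17), si:ch1073-190k2.1 (-6.48 and -6.89), zgc:114175 (-4.99 and -5.50) and the synaptonemal complex gene syce2 (-5.10 and -5.51). zgc:171242 had no UMI in the transplant (at least 60.1-fold and 53.1-fold lower), nor had comtd1 (at least 31.5-fold and 42.2-fold).

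The single male and the pool, both of the Sox17 strategy and of the same age, differed in the hormone list and in immediate early and glycolysis genes. Immediate early genes were lower in 16 of 20 cases in somatolactotroph-like cells of the single male, 13 with their interval (relative median -0.44; percentile 0.01), including socs3a (-1.34), btg2 (-0.88) and ier2b (-0.84). Glycolysis genes were lower in 14 of 17, 12 with their interval (-0.35; 0.08), with pkma at -0.84. Hormones were lower in 8 of 9 (-1.12; 0.00), and in 8 of 9 cases the interval lay below the shift too; most are made by other classes, and free RNA was not estimated; lhb had -2.09 here and -2.08 in all other cells. The remaining relative medians were -0.04 for secretory granule genes (43.1), -0.06 for transcription factors (48.8), 0.24 for receptors (91.3), -0.11 for heat shock (13.7), -0.25 for ER stress (2.07), -0.21 for mitochondrial (4.08), 0.14 for interferon (82.9) and -0.15 for clock genes (12.3). Higher single genes were the sialyltransferase gene st6galnac1.2 (3.62), si:dkey-35i13.1 (4.12), ENSDARG00000093349 (2.65), si:dkey-192g7.3 (2.47), si:dkey-79f11.7 (2.20) and tnn, a tenascin (1.99). Also higher were the plakophilin gene pkp1b (1.48), igfbp5b (1.49), znf384l (1.83) and the growth hormone receptor gene ghra (1.78).

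Lower in the single male than in the pool were the muscle creatine kinase gene ckmb (-6.20), the granulin gene grn1 (-3.49), lhb (-2.09) and the second scg5 (-3.85). The unnamed loci si:ch211-226h8.14 (-4.04), si:ch211-57b15.2 (-3.79), wu:fj16a03 (-2.95), CABZ01067657.1 (-2.88), CR339041.3 (-4.12) and si:ch211-237l4.6 (-2.88) were lower as well. In all other cells combined lhb was also lower in the single male (-2.08), whereas wu:fj16a03 was higher (0.52) and ckmb had -0.56 with an interval that held 0 (-1.60 to 0.39).

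**Figure D3:**
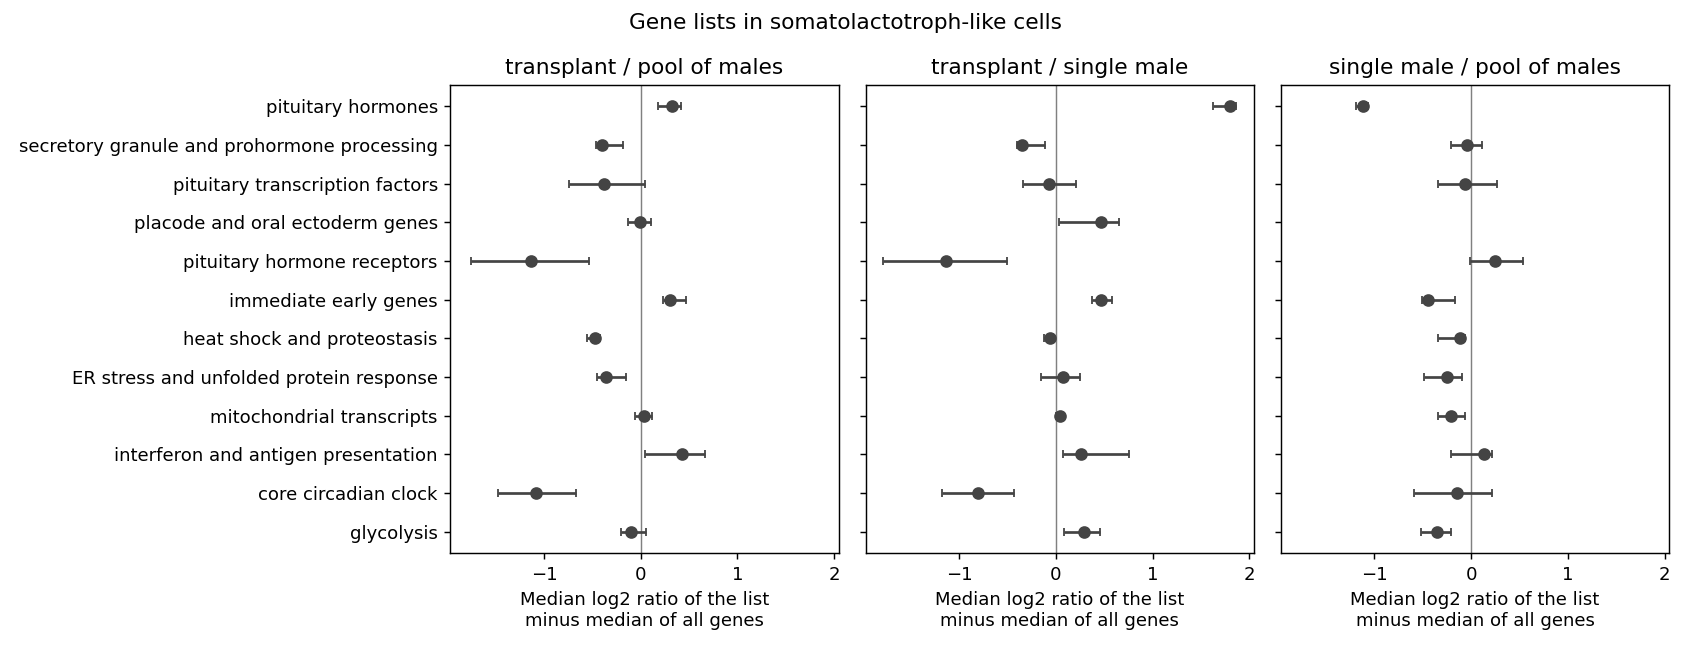
Median log2 ratio of 12 gene lists in somatolactotroph-like cells minus the median of all genes, with the median of the members' 95% count intervals, for transplant over pool, transplant over single male and single male over pool (panels). The clock list lies at -1.08 and -0.81 in the transplant panels and at -0.15 for single male over pool.

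Genes of early endoderm were all but silent in these adult cells. sox17, the gene whose promoter drove Cre, had 0 UMIs in the pool, 1 in the single male and 0 in the transplant, and foxa3, gata5 and hhex had none in any library. pax9 was the exception in that list, with 267 UMIs in 260 pool cells, 252 in 239 single-male cells and 129 in 124 transplant cells. Placode genes were widely seen: pitx3, a homeobox gene of the lens and pituitary placodes, was detected in 3303 pool, 2009 single-male and 3848 transplant cells, and eya1 in 2869, 1931 and 3467. The endoderm list and the cell cycle list had fewer than 5 measured members in the compared classes and were given no median.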

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

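All tests of explanations in this part were chosen after the results had been seen. In somatolactotroph-like cells the conversion share differed from the rest of the library by -2.86 percentage points in the pool and by 18.3 points in the single male. Melanotroph-like cells differed by -2.33 points in the pool and 21.6 points in the single male. For pomca-gad2 cells the differences were 2.22 and -18.9 points, and for thyrotroph-like cells 5.00 and -2.97 points. These pairs have opposite signs, but the difference between the libraries was not tested.

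mCherry UMIs in both Sox17 libraries could come from transcription through the EGFP cassette without recombination. At the pool's rate of 7.77 mCherry UMIs per 100 EGFP UMIs, 7.54 mCherry UMIs would be expected beside the 97 EGFP UMIs of the transplant, whose donor cells carry the cassette without Cre, and 0 were found. Free RNA in the droplets would give each class a like level, but in the single male mCherry per total UMIs was 4.31 times as high in stem-like as in gonadotroph-like cells (2.65 to 7.37). The first value argues against transcription through the cassette as the whole source of mCherry. The second argues against free RNA as the whole source in the single male alone. It sets the highest class against the lowest, picked by their values, which its interval does not cover. Free RNA was not tested in this way for the pool. Recombination outside the endoderm, or without tamoxifen, was not tested, since no fish with Cre but without tamoxifen was used here.

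In the transplant, 718 DsRedExpress UMIs were found, although the labels name no Cre for this library. Free RNA may be put aside as the whole source, because cells with TagBFP held DsRedExpress 32.6 times as often (17.7%; 16.3 to 19.2) as the rate in cells of the same class and depth without TagBFP gives. Transcription through the TagBFP cassette stays open: DsRedExpress was 5.02% (4.67 to 5.39) of host reporter UMIs, from 2.298% in gh1-high to 16.03% in stem-like cells, and a passage rate that differs between classes cannot be told apart from other sources in this library. No biological explanation was tested.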

How the results depend on the processing

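No paired analysis was possible because each design group is 1 library of different fish. Of the shares and medians repeated under settings chosen before the data were examined, 228 of 273 class shares, 197 of 208 conversion shares, 114 of 136 donor shares, 179 of 180 list medians within classes and 203 of 234 relative list medians between libraries stayed inside their interval. For settings added after seeing the data these were 242 of 312 class shares, 143 of 143 conversion shares, 87 of 88 donor shares and 27 of 27 list medians within classes. For list medians, the interval ran between the medians of the members' lower and upper bounds. It is about as wide as that of a single gene and is not an interval of the list median. The counts for list medians thus say little about how stable these medians are. Single genes between libraries stayed inside in 362 of 378 cases, with no change of sign past the interval. Within the single male they stayed inside in 327 of 355 planned cases, with 3 changes of sign, and in 88 of 108 added cases, with 4. Calling a reporter at 2 UMIs left no class for the comparison within a library, and the donor against host comparison had no value under any setting. Shares and list medians that left their interval follow by setting, with the genes that changed sign; other single genes that left it are given only by the counts above. The cause was not tested.

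Without a filter, unnamed cells were 7.91% of the pool. At 500 genes and 10.0% mitochondrial UMIs, the pool shares were 20.5% for somatolactotroph-like, 21.0% for pomca-gad2, 0.463% for pituicyte-like and 1.51% for unnamed cells. That filter gave 26.0%, 21.9%, 0.343% and 2.45% for these classes in the single male. For the transplant it gave 18.5% somatolactotroph-like, 7.10% pomca-gad2, 3.56% stem-like, 0.421% pituicyte-like, 0.191% mural-like and 3.11% unnamed cells. With doublets kept, prl-high cells were 9.22% of the transplant, and the hormone list of single male over pool had a relative median of -1.06. Doublets kept also changed signs in the single male: prl in somatolactotroph-like cells came to -0.27, and in pomca-gad2 cells gh1 to 0.83, tshba to 0.36 and the hormone median to 0.30.

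At 2 UMIs per reporter, the conversion share was 21.3% in pool prl-high cells, 47.8% in the whole single male and 17.3% in its pomca-gad2 cells. Donor shares at 2 UMIs were 0.750% in all cells, 2.07% prl-high, 0.907% somatolactotroph-like, 0% melanotroph-like, 0.752% pomca-gad2 and 1.66% gonadotroph-like. As a share of reporter UMIs, the donor mark was 0.673% in all cells, 1.80% in prl-high, 0.939% in somatolactotroph-like, 0.0666% in melanotroph-like, 1.99% in pomca-gad2 and 1.004% in gonadotroph-like cells.

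Thinning to 1500 UMIs gave single-male conversion shares of 61.8% in somatolactotroph-like and 79.1% in stem-like cells. Donor shares were then 1.73% in all cells, 0% in melanotroph-like and 0.952% in gonadotroph-like cells. After that thinning, transplant over single male had relative medians of 1.49 for hormones, 0.59 for immediate early, -0.17 for heat shock, -0.15 for ER stress and -0.035 for mitochondrial genes. Transplant over pool had -0.56 for heat shock and -0.011 for interferon genes. Thinning to 1000 UMIs, which left out 757, 636 and 502 cells of pool, single male and transplant, gave pool conversion shares of 0% in melanotroph-like and 4.17% in thyrotroph-like cells. Single-male shares were 43.9% in all cells, 58.4% prl-high, 33.0% pomca-gad2 and 80.0% stem-like. Donor shares at 1000 UMIs were 1.25% in all cells, 2.05% somatolactotroph-like, 0% melanotroph-like, 1.27% gonadotroph-like and 0% thyrotroph-like. At 3000 UMIs, which left out 4652, 3813 and 2427 cells, they were 1.498% in all cells and 1.77% in somatolactotroph-like cells.

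At Leiden resolution 0.5, with names carried over or given afresh, pomca-gad2 cells were 23.2% of the pool, 22.9% of the single male and 7.91% of the transplant. Mural-like cells were then 0% in each library, unnamed cells 1.92%, 2.66% and 2.97%, and endothelial-like cells 0.919% of the transplant. Leiden resolution 2.0 gave 7.74% unnamed cells in the pool and 9.55% prl-high cells in the transplant. With each library clustered alone, the pool had 0% mural-like and 8.22% unnamed cells. The single male then had 14.6% prl-high, 24.1% somatolactotroph-like, 0% mural-like, 0% macrophage-like and 6.36% unnamed cells, and the transplant 19.0% gh1-high, 7.96% pomca-gad2, 25.3% gonadotroph-like and 2.99% unnamed cells. Leaving hormone genes out of the clustering gave 17.5% pomca-gad2 and 7.70% unnamed cells in the pool, 0.989% endothelial-like cells in the transplant and 0% macrophage-like cells in all 3 libraries.

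The second naming rule, added after seeing the data like the settings with fresh names below, gave 23.2%, 22.9% and 7.90% pomca-gad2 cells and 2.42%, 3.03% and 2.97% unnamed cells in pool, single male and transplant. Fresh names at Leiden 2.0 gave the pool 14.1% prl-high, 5.74% gh1-high, 0% stem-like and 18.4% unnamed cells, and the single male 13.8%, 5.45%, 0% and 20.4%. The transplant had 10.3% gh1-high, 0% stem-like and 13.4% unnamed cells. Fresh names with libraries clustered alone left 0% stem-like, 0% mural-like and 12.6% unnamed cells in the pool. For the single male they gave 14.6% prl-high, 24.1% somatolactotroph-like, 12.7% pomca-gad2, 0% mural-like, 0% macrophage-like and 12.8% unnamed cells. For the transplant they gave 10.8% gh1-high, 7.96% pomca-gad2, 5.41% gonadotroph-like, 0% stem-like and 35.2% unnamed cells, and a gonadotroph-like donor share of 6.36%.

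Fresh names without hormone genes gave 14.9% pomca-gad2, 0% endothelial-like, 0.375% macrophage-like and 11.3% unnamed cells in the pool. They gave 0% endothelial-like, 0.404% macrophage-like and 9.17% unnamed cells in the single male, and 0%, 0.989% and 5.06% in the transplant. Fresh names under the strict filter differed from the carried ones in the transplant, with 15.5% gh1-high and 8.21% unnamed cells. With doublets kept, fresh names left 7.92%, 8.27% and 5.54% unnamed cells in pool, single male and transplant, and with no filter 7.91% in the pool.

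Without the highest cell of each group, added after seeing the data, cga in prl-high cells came to 0.031, and in pomca-gad2 cells prl came to -0.21 and tshba to 0.25. Without cells of 3 or more UMIs of the second scg5, lhb in pomca-gad2 cells came to 0.49.

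With no count minimum, relative medians of transplant over pool were 0.61 for hormones, 0.27 for placode, -0.10 for receptor, -0.28 for heat shock, -0.085 for ER stress, 0.26 for mitochondrial, 0.70 for interferon, -0.65 for clock and 0.16 for glycolysis genes. Those of transplant over single male were 2.12 for hormones, -0.043 for secretory granule, 0.95 for placode, -0.23 for receptor, 0.68 for immediate early, 0.26 for heat shock, 0.20 for mitochondrial and 0.62 for glycolysis genes. Single male over pool had 0.33 for transcription factors and -0.071 for receptors. With at least 100 UMIs, transplant over single male had -0.47 for secretory granule, -0.19 for heat shock and -0.078 for mitochondrial genes, and transplant over pool -0.18 for interferon genes. The median shift of all genes, -0.37 and -0.32 for the transplant, was 0.03 and 0.09 under median-ratio scaling and -0.17 and -0.11 without hormone genes in the total.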

Other observations

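The tests of the scg5 pattern below were chosen after the pattern had been seen. Heat shock genes were lower in the transplant than in the pool in gonadotroph-like (relative median -2.02; 9 of 13 genes), thyrotroph-like (-1.92; 10 of 13), melanotroph-like (-1.57; 10 of 13) and stem-like cells (-0.94; 12 of 14), each at percentile 0.00. Against the single male these medians were -0.60, -0.022, -0.029 and -0.61. Immediate early genes, which had no common direction in somatolactotroph-like cells, were lower than in the pool in 19 of 20 cases in gonadotroph-like cells (-1.28; percentile 0.00) and 15 of 19 in thyrotroph-like cells (-0.85; 0.01). In melanotroph-like cells 17 of 18 were higher than in the single male (1.40; percentile 100).

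In the pool, 347 of 1364 somatolactotroph-like cells (25.4%; 23.1 to 27.8) held at least 3 UMIs of the second scg5, against 21 of 1239 (1.69%; 1.05 to 2.58) in the single male and 0 of 1516 in the transplant, a limit of 0.198%. Over all classes these were 1197 cells (15.5%) of the pool and 51 cells (0.935%) of the single male. The pool cells had a median of 43 UMIs of the second gene but 1 of the first, whereas the other pool cells had a median of 37 of the first. Most somatolactotroph-like cells of the pool thus held transcripts of one scg5 or the other.

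The second scg5 gene in few cells of the single male could mark cells of another fish, an explanation found from the same data. Reads shared at a fixed rate between the 2 scg5 genes would leave the first gene at its usual level, but its median in these cells was 1, against 26 in the rest. Barcodes shared with the pool are no source, since 1 of the 51 cells had such a barcode. The 7 other named genes that were low both in somatolactotroph-like and in all other cells of the single male were 2.79 times as high per total UMIs in these cells as in its other cells (2.66 to 2.93). Of those 1639 UMIs lhb made 1573, and 1 pomca-gad2 cell alone held 1103 lhb UMIs. This ratio thus rests mostly on 1 cell, and its interval covers counting error only, so it decides nothing about the 51 cells. A second form without hormones and gonadotroph-like cells was added and gave 6.34 (4.73 to 8.33). In the pool these forms gave 0.623 (0.616 to 0.629) and 1.27 (1.197 to 1.36). With all 9 other named low genes, ckmb and wu:fj16a03 included, somatolactotroph-like cells alone gave 3.48 (2.85 to 4.21). Over more classes these 9 genes gave 2.22 (2.12 to 2.33) and, without hormones and gonadotroph-like cells, 0.765 (0.648 to 0.898); these forms decide nothing, since wu:fj16a03 is not low in the other classes of the single male. Whether the 2 identifiers are separate genes or alleles of one gene stays open.

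These 51 cells held EGFP more often (13 cells, 25.5%) than the other single-male cells (12.1%), and mCherry in 1 cell (1.96%) against 8.59%. Without cells of 3 or more UMIs of the second scg5, the medians for mCherry-only over EGFP-only somatolactotroph-like cells were -0.35 for immediate early genes and -0.59 for clock genes in the single male. smtla then came to 1.27 and smtlb to -1.39. Whether the 15.5% of pool cells belonged to 1 of the 6 fish was not tested, nor was any biological explanation.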
